A study of Homo sapiens with 6 samples.

How the data were processed

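The series holds 6 human 2-colour spotted arrays, 3 of siELOVL7 over siCONTROL in C4-2B cells and 3 of HFD over ND in ELOVL7-overexpressing tumours. The treated RNA carried Cy5 and the control RNA Cy3 on every array, per the labels, with no dye swap. RNA was amplified in 2 rounds with T7 polymerase before labelling, per the labels' protocols. The scanner software, background correction and normalization are not given in the sources used here. The authors deposited 1 log ratio per spot and array, taken here as log2 of Cy5 over Cy3. The base is not stated: measured values run from -6.94 to 6.12, which no base 10 ratio would reach, and a natural log is not excluded. The direction follows the dyes in the labels, and ELOVL7 lay below 0 on 3 of 3 knockdown arrays. The description of the tumour arrays repeats the siRNA text, so their group was taken from the titles and channel labels. The cell line behind the tumours is not given in the sources used here. The label of siELOVL7 array 3 names the control RNA of array 2, and averaging those arrays is among the alternatives. Each hybridisation was repeated 3 times per comparison, and nothing says that the RNAs came from separate cultures or mice, so p-values measure the spread between these arrays, which may be technical.

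Of 36863 spots in the deposited table, 12092 were blank on all 6 arrays and 12476 were measured on all 6. Another 8685 spots carried, on some or all arrays, a constant with at most 9 decimals that was identical wherever it recurred in the spot (31156 values, of which 29560 recurred). These values, between 17.6% and 30.7% of the filled values of an array, were treated as substituted and left out. That choice was made after the file was examined and departs from the plan to use values as deposited. With them kept, 1370 genes rose and 4042 fell with siELOVL7, and 894 rose and 4682 fell on the high fat diet. After this step 15358 to 18811 spots were measured per array. The files hold no intensities, so the signal behind a spot is unknown and the number of arrays limits precision. A probe table paired 21714 spots with 1 gene symbol, 124 with several and left 15025 unnamed here. Symbols of 21640 spots were matched by gene id to the RefSeq gene table and updated. Spots of a symbol were averaged per array (3496 tested genes had over 1 spot), and spots with several symbols or none were left out.

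Genes with a value on all 3 arrays of a comparison were tested, 8758 for siELOVL7, 9626 for HFD and 8005 in both. One limma model with a mean per comparison was fitted to all 6 arrays (lmFit and eBayes, limma 3.58.1, R 4.3.3, 4 residual degrees of freedom), so that both comparisons share the estimate of spread. Each mean was tested against 0 and the difference of the means against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. Arrays were not centred in the main fit. The median of the gene means was -0.20 for siELOVL7 and -0.29 for HFD, and results after centring each array on its median stand beside the main ones. Overlaps of calls were tested with Fisher's exact test, 2-sided. Before the data were examined, 24 gene lists were fixed, 7 of them cell type markers, and tested with camera (preset correlation 0.01, Benjamini-Hochberg over 23 lists with at least 3 genes; the endothelial list had fewer) on the genes measured on all 6 arrays.

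The lists cover fatty acid synthesis, elongation and desaturation, sphingolipids and phospholipids, cholesterol, steroid hormones, lipid transport, fatty acid oxidation, androgen receptor targets and the cell cycle. Others cover p53 and apoptosis, endoplasmic reticulum stress, interferon, hypoxia and glycolysis, growth factors, inflammation, ribosomal proteins and the respiratory chain. The marker lists cover stroma, endothelium, leukocytes, adipocytes, blood with muscle and skin, luminal prostate, and basal and neuroendocrine prostate. The named genes follow a rule fixed beforehand. It takes ELOVL7, then the 10 largest mean changes each way with an adjusted p under 0.05 and the same sign on all 3 arrays, up to 6 members of a list by smallest p (the 2 smallest where none passed), the 5 largest differences each way, and up to 10 genes per pair of directions in the overlap. The other ELOVL genes, FASN, KLK3, list members that make up a count of 5 or fewer, and WIPI1 and CENPN among the differences were named after their values were seen.

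Alternatives fixed beforehand were centring, scaling to 1 median absolute deviation, testing each spot, other demands on missing values, array weights, robust moderation, other thresholds, fitting a comparison's arrays alone, averaging siELOVL7 arrays 2 and 3, an estimated correlation or fry for the lists, the replicate number as a block, and leaving out each array. Alternatives added after the data were seen kept the substituted values, centred each block of spots, used only spots measured on all 6 arrays, took 2 sets of arrays as a batch, and changed the demand on missing values for the difference. On simulated data with the arrays' own spread over 8005 genes, the siELOVL7 test recovered 32% of 50 genes changed by 0.5, 82% of those changed by 1 and 100% of those changed by 2, with 5 false calls. The test of the difference recovered 0%, 44% and 98%, with 4 false calls. The simulated noise was independent between genes and held no array offset and no spot or dye effect. These false calls therefore do not measure how many of the real calls are false. Labels were read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.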

Results

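Gene expression was compared on 6 human 2-colour spotted arrays in a study of ELOVL7, an enzyme that lengthens long-chain fatty acids, in prostate cancer. On 3 arrays, RNA of C4-2B cells transfected with an siRNA against ELOVL7 (siELOVL7, Cy5) was hybridised against RNA of cells given a control siRNA (siCONTROL, Cy3), 48 hours after transfection. C4-2B is an androgen-independent human prostate cancer line derived from LNCaP. On the other 3 arrays, RNA of ELOVL7-overexpressing tumours grown in mice on a high fat diet (HFD, Cy5) was hybridised against RNA of such tumours from mice on a normal diet (ND, Cy3). Between 15358 and 18811 of 36863 spots were measured per array, which gave values for 9496 to 11070 named genes. Their number, 3 arrays per comparison, limits the precision. Values are mean log2 ratios of Cy5 over Cy3 ± SD over 3 arrays, taken as base 2 because the range of the deposited values ruled out base 10. If they were natural logs, fold changes would be larger and every test would stay as given.

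The knockdown comparison asks which transcripts change when prostate cancer cells lose ELOVL7. ELOVL7 itself fell on 3 of 3 arrays, with log2 ratios of -0.87, -0.90 and -1.18 (mean -0.98 ± 0.17, adjusted p = 0.00606, limma). It stayed lower after each array was centred on its median (-0.77, adjusted p = 0.00624). On all 3 tumour arrays the same spot held 1 constant (-0.13), treated here as substituted, so it gave no measured value there. Why it gave none in tumours that overexpress ELOVL7 was not tested. Of the related elongases, ELOVL1 fell by 0.73 ± 0.15 on the log2 scale and ELOVL4 fell by 0.69 ± 0.20, while ELOVL6 (-0.40 ± 0.04, adjusted p = 0.0827) did not pass. The ELOVL1 spot also lay below 0 on the tumour arrays (-0.79, -0.61 and -0.91). Its difference between the comparisons was 0.047 (limma, adjusted p = 0.977), so this fall is not particular to the knockdown. The difference for ELOVL4 was -0.52 and did not pass (limma, adjusted p = 0.445). The ELOVL4 mean includes a spot measured on siELOVL7 array 2 alone (-1.31). Its other spot read -0.56, -0.55 and -0.59 on the siELOVL7 arrays. The ELOVL5 spots disagreed. A spot read -0.61, -0.44 and -0.18 on the siELOVL7 arrays and another read 1.19, 0.98 and 0.94. A further spot read -0.61 and -0.18 on arrays 1 and 2 and held a substituted value on array 3. No direction is therefore given for ELOVL5.

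The largest rises with siELOVL7 were those of PCDH20, a protocadherin (log2 1.84 ± 0.18), TMEM45A, a transmembrane protein (1.72 ± 0.13), TMCO1, a calcium channel of the endoplasmic reticulum (1.67 ± 0.13), and SMS, spermine synthase (1.62 ± 0.06). ACADL, the long-chain acyl-CoA dehydrogenase of fatty acid oxidation (1.56 ± 0.17), and SPOCK1, an extracellular proteoglycan (1.54 ± 0.12), rose as well. KCNMA1, the pore of a calcium-activated potassium channel (1.48 ± 0.23), SERP1, a stress-associated protein of the endoplasmic reticulum (1.43 ± 0.22), LRIG1, a negative regulator of the EGF receptor (1.28 ± 0.14), and PLK2, a polo-like kinase (1.25 ± 0.11), completed the 10 largest rises. The largest fall was that of CAMK2N1, an inhibitor of calmodulin-dependent kinase II (-2.88 ± 0.23, adjusted p = 3.70e-04). It was followed by NPDC1 (-2.34 ± 0.74), the anion exchanger SLC4A2 (-2.17 ± 0.77), SHISA4 (-2.13 ± 1.58), the gelatinase MMP2 (-2.00 ± 0.60), and the transcription factor NFE2 (-2.00 ± 0.88). The receptor kinase EPHB3 (-1.98 ± 1.00), S100A14 (-1.97 ± 1.73), the interferon-induced IFIT2 (-1.91 ± 0.04), and MCUB, a subunit of the mitochondrial calcium uniporter (-1.86 ± 1.32), made up the rest. The adjusted p-values of these 20 genes ran from 3.70e-04 (CAMK2N1) to 0.0380 (SHISA4), and each gene had 1 sign on 3 of 3 arrays. SHISA4 did not pass with any array left out (adjusted p = 0.0559 without array 1, 0.172 without array 2 and 0.102 without array 3), nor did it after centring (0.0527). S100A14 was lost without array 1 (0.127) or array 2 (0.125), and MCUB (0.0529) and TMEM45A (0.0541) were lost without array 1. The mean of SHISA4 was -1.27 without array 2, that of S100A14 -1.30 without array 2, and that of MCUB -1.11 without array 3. SLC4A2, NFE2 and EPHB3 read lowest on array 3 (-3.06, -2.93 and -3.09). NPDC1, SLC4A2, NFE2 and EPHB3 fell further on the high fat diet (-3.99, -3.51, -2.99 and -2.95). MMP2 read -3.71 and -4.09 on HFD arrays 1 and 2. These falls are therefore not particular to the knockdown. CAMK2N1, SHISA4, S100A14, IFIT2 and MCUB did not pass on the diet.

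Over all 8758 genes tested, 1053 rose and 2179 fell with siELOVL7 at an adjusted p under 0.05 (limma). The median gene lay at log2 -0.21, -0.19 and -0.25 on the 3 arrays. Relative to those medians 2256 genes were higher and 1153 lower, so that 67.4% of the calls were falls as deposited and 33.8% after centring. In both scalings, 1053 genes rose and 1153 fell. The counts shrank to 134 and 359 without array 1, to 150 and 412 without array 2, and to 641 and 952 without array 3. The label of array 3 names the control RNA of array 2, and with those arrays averaged 402 genes rose and 738 fell.

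Of 47 measured cell cycle genes 20 rose with siELOVL7, 3 fell and 24 did not pass. The counts of rises and falls were the same when adjusted over the list alone, and 25 rose and 0 fell after centring. The spindle checkpoint genes MAD2L1 (log2 0.99 ± 0.13), BUB1 (0.91 ± 0.12) and BUB1B (0.86 ± 0.19), the mitotic kinase NEK2 (1.01 ± 0.17), the cyclin CCNA2 (0.94 ± 0.08) and the spindle protein DLGAP5 (0.87 ± 0.12) were the clearest. MCM5, CDK4 and CDK2, which act at or before DNA replication, read -0.54, -0.47 and -0.46 and passed only without centring. The list ranked high among all genes (camera with a preset correlation, adjusted p = 1.48e-05), but not when the correlation between genes was estimated from the arrays (adjusted p = 0.996 with an estimated correlation). That alternative ended every list call in both comparisons. It rests on 4 residual degrees of freedom, so it had little power, and its result does not decide whether a list moved.

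Genes of lipid metabolism moved both ways with siELOVL7. Among 16 measured genes of fatty acid elongation and desaturation, 6 fell and 1 rose (6 and 1 adjusted over the list alone; 5 and 3 after centring, camera adjusted p = 0.376). The desaturase-family gene FADS3 fell by 1.14 ± 0.04 and the acyl-CoA thioesterase ACOT7 fell by 1.01 ± 0.20, while the palmitoyl thioesterase PPT1 rose (0.40 ± 0.08). In fatty acid synthesis 2 of 15 genes rose and 4 fell (5 and 5 adjusted over the list alone; 5 and 3 after centring, adjusted p = 0.867), with the malic enzyme ME1 at 0.70 ± 0.18 and the desaturase SCD5 at 0.94 ± 0.51 against AGPAT2 at -0.96 ± 0.26 and DGAT1 at -0.62 ± 0.15, both of triglyceride synthesis. FASN, the fatty acid synthase, read -0.26 ± 0.07 and did not pass (adjusted p = 0.0901). In fatty acid oxidation 7 of 27 genes rose and 4 fell (7 and 7 adjusted over the list alone; 11 and 3 after centring, adjusted p = 0.570). The risers included ECI2 (0.89 ± 0.20), DECR1 (0.72 ± 0.10) and the medium-chain dehydrogenase ACADM (0.65 ± 0.04), and the very long-chain dehydrogenase ACADVL fell by 0.77 ± 0.07.

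Cholesterol synthesis genes split evenly with siELOVL7. SQLE (0.62 ± 0.04), ACAT2 (0.59 ± 0.05) and SC5D (0.47 ± 0.11) rose, and DHCR7 (-0.83 ± 0.22), TM7SF2 (-0.87 ± 0.28) and MVK (-0.81 ± 0.36) fell, out of 16 measured (3 and 3 adjusted over the list alone; 6 and 3 after centring). The list passed upwards (camera adjusted p = 0.0496; adjusted p = 0.996 with an estimated correlation) but not after centring (0.155), without array 2 (0.0539) or without array 3 (0.0956). Of 19 steroid hormone genes 3 rose and 7 fell (3 and 8 adjusted over the list alone; 7 and 3 after centring, adjusted p = 0.993). The 5-alpha-reductases went apart, SRD5A1 rising (0.91 ± 0.26) and SRD5A2 falling (-1.37 ± 0.69), and the cortisol-inactivating HSD11B2 fell by 1.39 ± 0.29. Lipid transport gave 4 rises and 7 falls in 16 genes (4 and 7 adjusted over the list alone; 5 and 2 after centring, adjusted p = 0.744), among them the lysosomal lipase LIPA (0.72 ± 0.22) and the HDL receptor SCARB1 (-0.81 ± 0.16). In sphingolipid and phospholipid synthesis 0 of 22 genes rose and 2 fell, PCYT2 (-0.76 ± 0.08) and PTDSS2 (-0.69 ± 0.22) (0 and 2 adjusted over the list alone; 4 and 2 after centring, adjusted p = 0.867; limma, 1 rise at an unadjusted p under 0.05). The list's median was -0.15 although its test pointed up; the same difference in sign held for fatty acid synthesis (-0.25), steroid hormones (-0.22) and fatty acid oxidation (-0.17).

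Androgen receptor targets gave 5 rises and 3 falls in 27 genes (5 and 3 adjusted over the list alone; 8 and 2 after centring, camera adjusted p = 0.151). FKBP5, an androgen- and glucocorticoid-induced chaperone, rose by 1.17 ± 0.11 and the prostate homeobox gene HOXB13 fell by 0.89 ± 0.12, while KLK3, which encodes prostate-specific antigen, read 0.21 ± 0.02 (adjusted p = 0.171; 0.42 and passing after centring). Their median was -0.0094 against a test pointing up. Interferon-response genes fell in 12 of 26 cases and rose in 1, EIF2AK2 (13 and 1 adjusted over the list alone; 7 falls and 3 rises after centring, adjusted p = 0.320). IFIT2 (-1.91 ± 0.04), IFI16 (-1.55 ± 0.60) and IFIT3 (-1.24 ± 0.26) fell most and EIF2AK2 read 0.67 ± 0.07. Endoplasmic reticulum stress genes gave 5 rises and 4 falls in 26 (5 and 4 adjusted over the list alone; 13 and 3 after centring, adjusted p = 0.112), with the stress kinase EIF2AK3 (0.68 ± 0.13) and HERPUD1 (0.78 ± 0.19) against calreticulin, CALR (-1.35 ± 0.92), and TRIB3 (-0.65 ± 0.18). The plot of list members shows 4 of these lists in both comparisons.

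**Figure D1:**
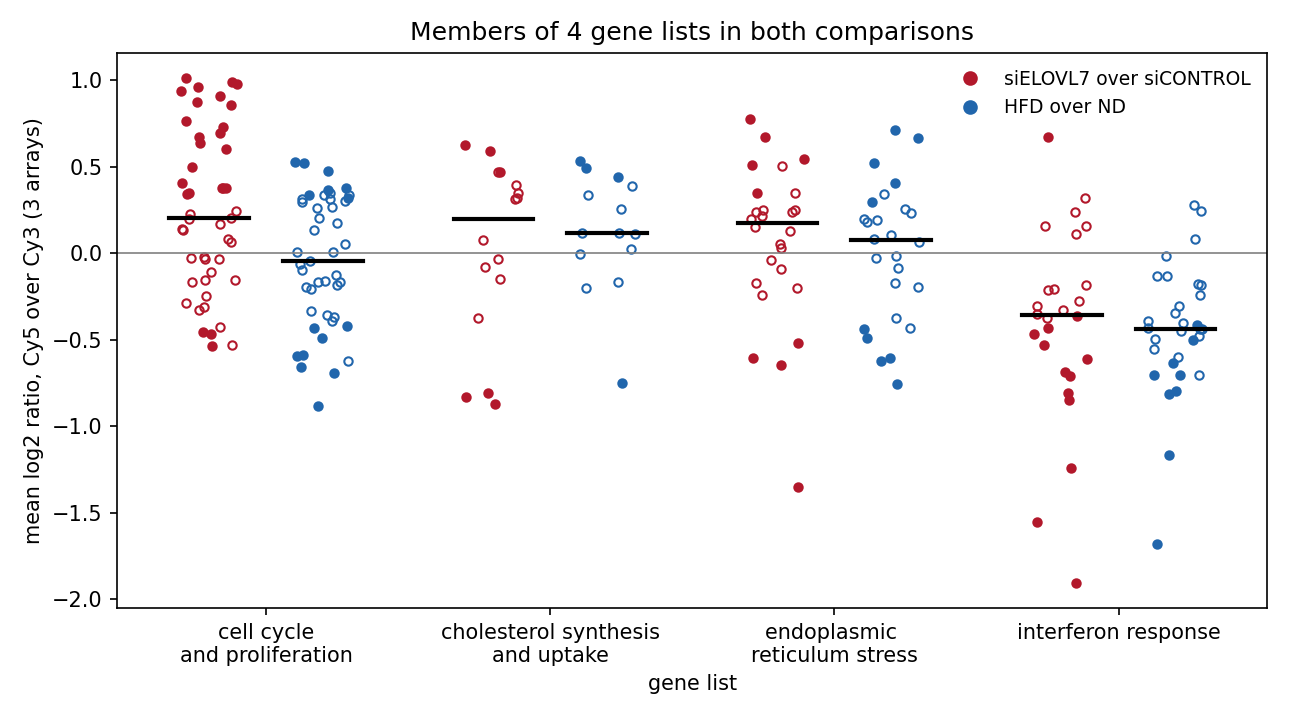
Mean log2 ratio of each measured member of the cell cycle, cholesterol, endoplasmic reticulum stress and interferon lists, for siELOVL7 over siCONTROL and for HFD over ND (mean of 3 arrays per point). The siELOVL7 cell cycle members lie mostly above 0 (20 rose, 3 fell), and the interferon members mostly below it (1 rose, 12 fell).

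The diet comparison asks which transcripts differ when ELOVL7-overexpressing tumours, which grew faster on a high fat diet per the labels, come from mice on that diet. The largest rises on the high fat diet were those of MYH4, a skeletal muscle myosin (log2 1.90 ± 0.71), the epithelial cadherin CDH1 (1.47 ± 0.08), the collagenase MMP1 (1.34 ± 1.02) and the adipocyte fatty acid-binding protein FABP4 (1.20 ± 0.26). The vasopressin receptor AVPR1A (1.18 ± 0.11), the heat shock protein HSPH1 (0.99 ± 0.04), the RNA cap-binding NCBP1 (0.99 ± 0.24), the receptor GPR37 (0.96 ± 0.31), the laminin-binding integrin ITGA6 (0.91 ± 0.33) and PCDH20 (0.90 ± 0.42) also rose. The largest falls were those of NPDC1 (-3.99 ± 0.23), SLC4A2 (-3.51 ± 0.33), the co-repressor subunit GPS2 (-3.41 ± 0.49), the forkhead factor FOXO4 (-3.34 ± 0.33), and INTS1 of the integrator complex (-3.22 ± 0.40). MN1 (-3.20 ± 0.35), the Kell blood group gene KEL (-3.10 ± 0.50), the homeobox gene LHX2 (-3.03 ± 0.04), NFE2 (-2.99 ± 0.19) and EPHB3 (-2.95 ± 0.46) completed the 10 largest falls. Adjusted p-values of these 20 genes ran from 9.07e-04 (NPDC1) to 0.0404 (MMP1). MMP1 did not pass without array 1 (0.0812), array 2 (0.118) or array 3 (0.0512). Its mean was 0.83 without array 1 and 1.85 without array 3. AVPR1A was lost without array 1 (0.0569) or array 3 (0.0920), and GPR37 (0.0503) and PCDH20 (0.0722) were lost without array 3. With array weights 14 of the 20 passed, and AVPR1A, GPR37, GPS2, MMP1, MN1 and PCDH20 did not.

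Over all 9626 genes tested on the tumour arrays, 547 rose and 3048 fell on the high fat diet (limma, adjusted p under 0.05). The median gene lay at log2 -0.53, -0.04 and -0.33. Relative to those medians 1968 genes were higher and 1074 lower, so that 84.8% of the calls were falls as deposited and 35.3% after centring. In both scalings, 547 genes rose and 1074 fell. The falls numbered 1609 without array 1 and 518 without array 3, and the rises 53 without array 3. With the tumour arrays fitted alone, without the spread of the siELOVL7 arrays, 134 rose and 1493 fell, and with array weights 25 rose and 408 fell.

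In the tumours 7 of 45 cell cycle genes rose on the high fat diet and 8 fell (6 and 8 adjusted over the list alone; 16 and 2 after centring). The thymidylate synthase gene TYMS rose (0.52 ± 0.17), while MCM5 (-0.89 ± 0.10), the licensing factor CDT1 (-0.69 ± 0.10) and MYBL2 (-0.66 ± 0.22) fell. The list passed upwards although its median was -0.04 (camera adjusted p = 0.0208; adjusted p = 0.997 with an estimated correlation), but not after centring (0.0809) or without array 1 (0.352). Of 14 cholesterol genes INSIG1 (0.53 ± 0.40), SC5D (0.49 ± 0.21) and ACAT2 (0.44 ± 0.22) rose and TM7SF2 fell (-0.75 ± 0.47) (3 and 1 adjusted over the list alone; 4 and 0 after centring). That list passed upwards too (0.0131; adjusted p = 0.997 with an estimated correlation), and lost its call after centring (0.0871) or without array 1 (0.375). Among 26 endoplasmic reticulum stress genes 5 rose and 5 fell (5 and 5 adjusted over the list alone; 13 and 0 after centring). The chaperone HSPA5 (0.71 ± 0.10), HERPUD1 (0.67 ± 0.47) and the transcription factor XBP1 (0.52 ± 0.15) rose, and PPP1R15A (-0.76 ± 0.28) and CHAC1 (-0.60 ± 0.23) fell. The list passed (0.0208; adjusted p = 0.997 with an estimated correlation), but not after centring (0.0809) or without array 1 (0.0621).

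Of 15 fatty acid synthesis genes measured on the high fat diet, 6 fell, ACSL1 rose (0.37) and 8 did not pass (6 and 1 adjusted over the list alone; 3 and 4 after centring, camera adjusted p = 0.997). DGAT2 (-1.15 ± 0.48), ACSL5 (-0.97 ± 0.37) and DGAT1 (-0.84 ± 0.15) fell, and FASN fell by 0.56 ± 0.18 but did not pass after centring (adjusted p = 0.0808). In elongation and desaturation 0 of 16 genes rose and 5 fell (limma, 1 rise at an unadjusted p under 0.05; 0 and 5 adjusted over the list alone; 3 and 2 after centring, camera adjusted p = 0.997), led by FADS3 (-1.24 ± 0.16) and ELOVL1 (-0.77 ± 0.15). Fatty acid oxidation gave 1 rise, ETFA (0.34), and 8 falls in 27 genes (0 and 6 adjusted over the list alone; 7 and 2 after centring, adjusted p = 0.903), with ACADS (-0.93 ± 0.75) and ACADVL (-0.65 ± 0.30) below 0. Lipid transport gave 2 rises, FABP4 and the cholesterol carrier NPC2 (0.45 ± 0.04), and 6 falls in 18 genes (2 and 6 adjusted over the list alone; 5 and 1 after centring, adjusted p = 0.903). Steroid hormone genes gave 1 rise, UGT2B11 (0.35 ± 0.07), and 7 falls in 20 (1 and 8 adjusted over the list alone; 7 and 3 after centring, adjusted p = 0.997), SRD5A2 falling by 1.83 ± 0.39. In sphingolipid and phospholipid synthesis SGMS1 rose (0.64 ± 0.09) and 3 of 24 genes fell (1 and 1 adjusted over the list alone; 5 and 0 after centring, adjusted p = 0.903).

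Androgen receptor targets gave 0 rises and 5 falls in 20 genes on the high fat diet (limma, 1 rise at an unadjusted p under 0.05; 0 and 2 adjusted over the list alone; 5 rises and 0 falls after centring, camera adjusted p = 0.972), with HOXB13 at -0.75 ± 0.15 and STEAP4 at -0.59 ± 0.35. Interferon-response genes gave 0 rises and 9 falls in 31 (limma, 0 rises at an unadjusted p under 0.05 too; 0 and 7 adjusted over the list alone; 2 and 3 after centring, camera adjusted p = 0.616), led by RSAD2 (-1.68 ± 0.99) and IFI16 (-1.16 ± 0.41). The medians of the oxidation, steroid, lipid transport, sphingolipid and androgen lists were -0.34, -0.31, -0.27, -0.06 and -0.21 while their tests, which rank a list against all other genes, pointed up.

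As deposited, the listed markers of stroma, endothelium, leukocytes, adipocytes, blood, muscle and skin that passed were lower on the high fat diet, FABP4 excepted. Medians of the stroma, endothelium and leukocyte lists also lay below 0 in the cultured C4-2B cells of the knockdown, at -0.46, -0.49 and -0.48. The tumours grew in mice and the arrays are human, so these falls do not show a change in the cells of the tumours. The skeletal muscle myosin MYH4, which is in none of the lists, rose (1.90 ± 0.71). The 4 measured endothelial genes fell (4 adjusted over the list alone; 3 after centring), among them ROBO4 (-1.42 ± 0.48), RAMP2 (-1.21 ± 0.52) and the VEGF receptor FLT1 (-0.95 ± 0.10). Of 12 blood, muscle and skin genes 4 fell and 0 rose (limma, 1 rise at an unadjusted p under 0.05; 5 and 0 adjusted over the list alone; 3 and 0 after centring, camera adjusted p = 0.997), namely the haemoglobin genes HBB (-1.88 ± 0.76) and HBA2 (-1.14 ± 0.67), the haem synthesis enzyme ALAS2 (-1.25 ± 0.39) and MYH2 (-0.65 ± 0.26). Stroma genes gave 5 falls in 18 (4 adjusted over the list alone; 1 fall and 1 rise after centring, adjusted p = 0.903), led by the collagen COL6A2 (-2.19 ± 0.73). Of 7 leukocyte genes CD3D (-0.65 ± 0.21) and CD68 (-0.53 ± 0.31) fell (4 adjusted over the list alone; 1 after centring, adjusted p = 0.903). In the adipocyte list FABP4 rose and CFD fell (-0.55 ± 0.09) out of 5 genes (1 and 3 adjusted over the list alone; 1 and 0 after centring, adjusted p = 0.903).

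Of 8 luminal prostate genes CDH1 rose on the high fat diet and KRT8 (-0.51 ± 0.34), KRT19 (-0.55 ± 0.05) and HOXB13 fell (1 and 4 adjusted over the list alone; 1 and 0 after centring, adjusted p = 0.903). Basal and neuroendocrine genes gave 5 falls in 11 (7 adjusted over the list alone; 2 after centring, adjusted p = 0.326), led by the peptide GRP (-1.51 ± 0.08) and the granin SCG3 (-0.84 ± 0.29). The medians of the luminal and stroma lists were -0.40 and -0.29 while their tests pointed up.

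Both comparisons together ask whether genes that fall without ELOVL7 rise on the diet. Of 8005 genes tested in both, 3 fell with siELOVL7 and rose on the high fat diet, where independent lists would share 123: AMIGO2, a neuronal adhesion protein (log2 -0.95 ± 0.01 against 0.86 ± 0.14), S1PR3, a sphingosine-1-phosphate receptor (-1.29 ± 0.04 against 0.31 ± 0.16), and the glucuronosyltransferase gene UGT2B11 (-0.39 ± 0.03 against 0.35 ± 0.07). AMIGO2 and S1PR3 kept opposite calls after centring. Another 8 genes rose with siELOVL7 and fell on the diet, where 310 would be shared by independent lists: ARHGAP28 (0.74 ± 0.39), TOB2 (0.66 ± 0.33), RAB27A (0.73 ± 0.22), PCM1 (0.45 ± 0.24), MLEC (0.42 ± 0.16), CENPN (0.69 ± 0.03), TFDP2 (0.36 ± 0.19) and EGFR, the EGF receptor (0.64 ± 0.05 against -0.35 ± 0.08 on the diet). None of these 8 had opposite calls in both scalings. After centring 11 genes fell with siELOVL7 and rose on the diet and 11 did the reverse.

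Most calls went the same way in both comparisons. A shared rise was found for 371 genes (61.3 expected of independent lists; Fisher's exact test, 2-sided, p = 9.43e-253), among them GPR37, HSPH1, CDH1, PCDH20, ITGA6, PHTF2, OIP5, SPCS2, SLC39A10 and GFPT1. Both lists of calls rest on 1 shared estimate of spread per gene, so they are not independent. Fisher's test also takes each gene as a unit, so its p-value does not measure replication. A shared fall was found for 1462 genes (622 expected), among them NPDC1, SLC4A2, NFE2, EPHB3, MOB3A, MN1, PTPN11, GOLGA6A, LYRM4 and ACTC1. LYRM4 and ACTC1 owed most of their siELOVL7 means to array 3 (-3.34 and -3.30, against -0.62 and -0.63 for LYRM4 and -0.75 and -0.66 for ACTC1 on arrays 1 and 2). After centring neither passed with siELOVL7 (adjusted p = 0.0854 and 0.0590). After centring 1393 genes shared a rise and 462 a fall. Across the 8005 genes, which are not independent replicates, the mean ratios correlated at r = 0.725 (Spearman's rho 0.766), and arrays correlated at a mean of 0.698 within and 0.581 between comparisons. The 1833 genes called the same way became 311, 359 and 825 without siELOVL7 array 1, 2 or 3, and 1202, 2924 and 338 without HFD array 1, 2 or 3. In both comparisons the treated RNA always carried Cy5, with no dye swap, so a dye effect of a spot stays in both ratios.

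Genes with more than 1 spot showed how far these ratios belonged to the gene. Over all 6 arrays, the mean ratios of a pair of spots of a gene correlated at 0.408 when both carried the same accession (95% bootstrap interval 0.339 to 0.477, 712 genes) and at 0.172 when they carried different accessions (0.0848 to 0.259, 554 genes). Spots of different genes gave -0.0455. Between the comparisons, the same spot correlated at 0.690 in the genes with different accessions, but a spot with the other spot of its gene at 0.0996. In the genes with spots of the same accession these values were 0.699 and 0.297. Within the knockdown comparison spots with different accessions correlated at 0.234, within the diet comparison at 0.0716, and for the difference of the comparisons at 0.177. For spots with the same accession these values were 0.518, 0.297 and 0.370, so part of the difference may also belong to the spot.

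**Figure D2:**
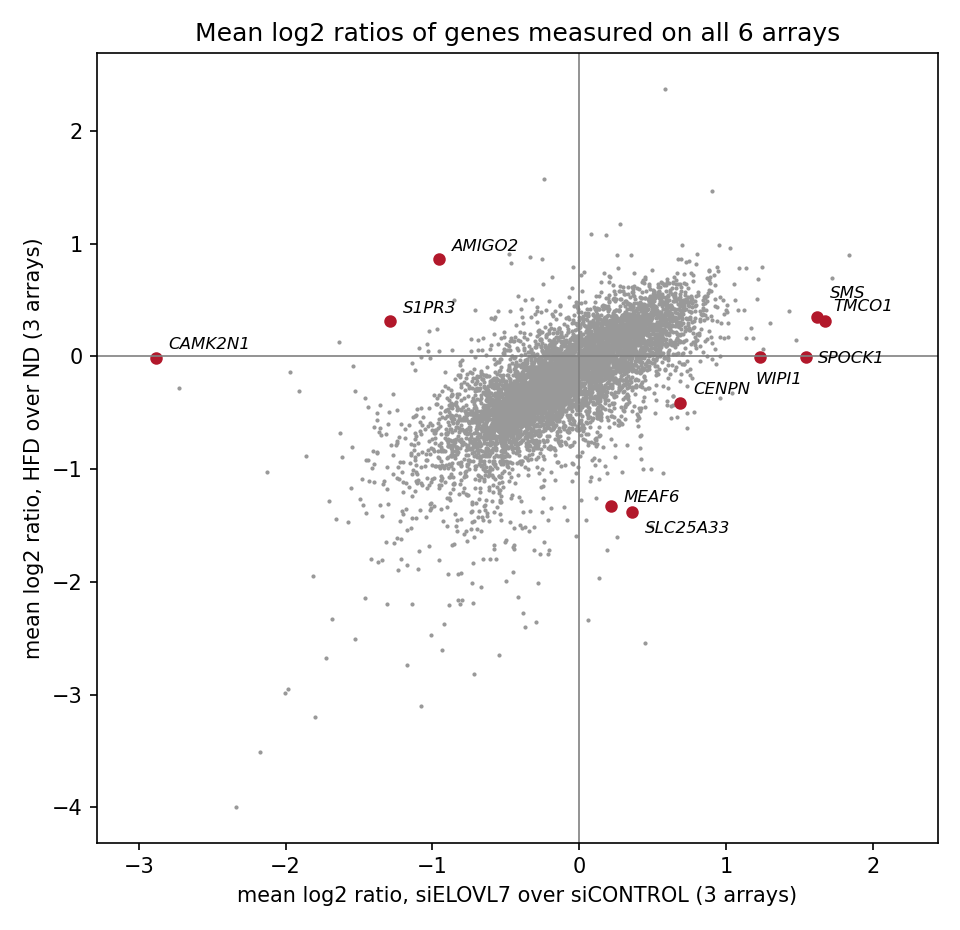
Mean log2 ratio of each of 8005 genes in the siELOVL7 comparison (horizontal axis) and the HFD comparison (vertical axis), 3 arrays each, with the 10 genes whose ratios differed named. Most genes follow the diagonal (r = 0.725 across genes), and CAMK2N1 lies far from it at -2.88 and -0.011.

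The difference of the comparisons, in which an effect of the same size on all arrays cancels, asks where the knockdown and the diet part. It passed for 10 genes, 7 higher and 3 lower in the knockdown ratio (limma, adjusted p under 0.05; 898 genes at an unadjusted p under 0.05). CAMK2N1 differed most (-2.87, SE 0.19, adjusted p = 0.00458), falling with siELOVL7 and lying at -0.011 ± 0.23 in the tumours. AMIGO2 (-1.82, SE 0.14) and S1PR3 (-1.60, SE 0.15) differed in the same sense. SLC25A33, a mitochondrial pyrimidine carrier (1.74, SE 0.18), and MEAF6, a subunit of histone acetyltransferase complexes (1.54, SE 0.19), fell on the diet (-1.38 ± 0.24 and -1.32 ± 0.18). After centring both also passed as higher with siELOVL7 (0.58, adjusted p = 0.00498, and 0.43, adjusted p = 0.0247). SPOCK1 (1.55, SE 0.19), TMCO1 (1.36, SE 0.15), SMS (1.27, SE 0.15) and the autophagy protein WIPI1 (1.24, SE 0.16) rose with siELOVL7, and CENPN, a centromere protein (1.10, SE 0.14), also fell on the diet. Adjusted p-values beyond CAMK2N1 ran from 0.00961 (AMIGO2) to 0.0494. After centring 9 genes passed, and SPOCK1 (0.130), SMS (0.130) and CENPN (0.0768) did not. The count became 1 without siELOVL7 array 1, 1 without array 2 and 59 without array 3, and 0 without HFD array 2 or 3 (1502 and 604 genes at an unadjusted p under 0.05).

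**Figure D3:**
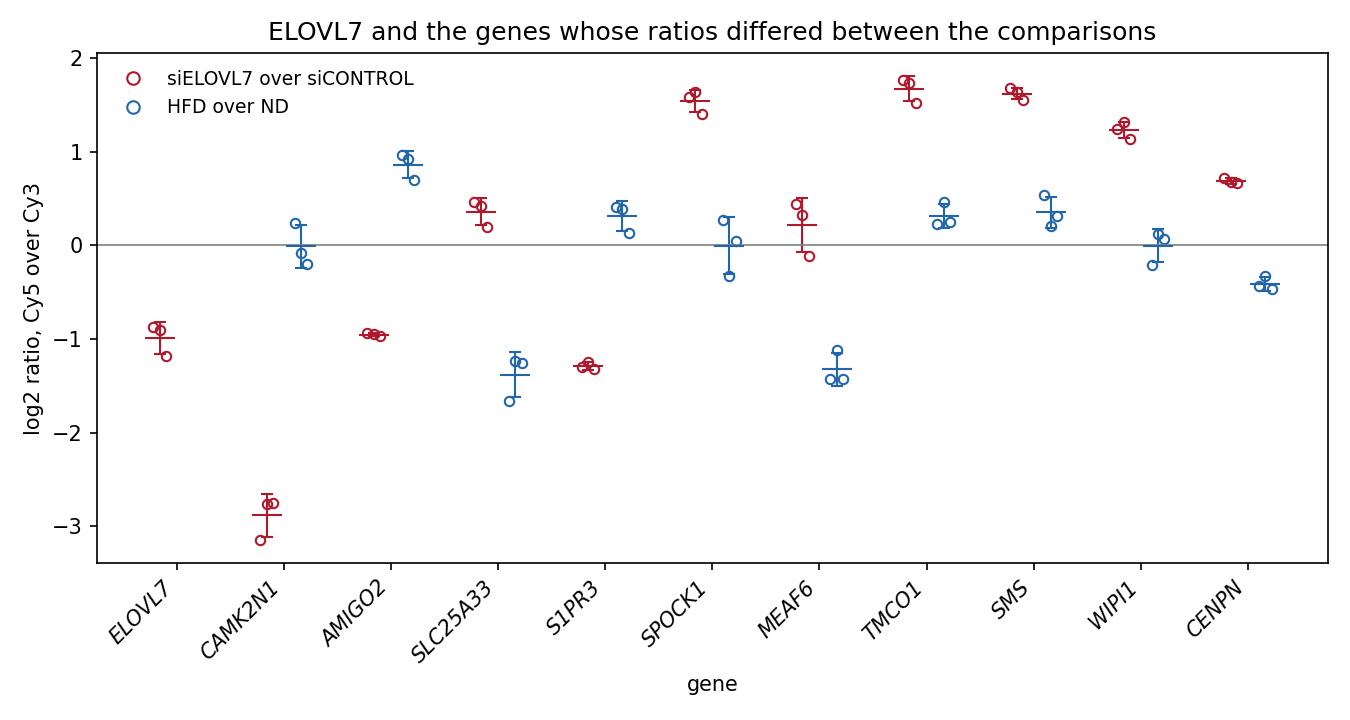
Log2 ratios of ELOVL7 and of the 10 genes whose ratios differed, with a circle per array and the mean ± SD of 3 arrays, for siELOVL7 over siCONTROL and HFD over ND. ELOVL7 lies between -0.87 and -1.18 on the siELOVL7 arrays and has no measured tumour value.

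Of the gene lists, the cell cycle list differed between the comparisons (camera adjusted p = 1.47e-04; adjusted p = 0.768 with an estimated correlation), with a median difference of 0.27 over 43 genes, higher with siELOVL7. Of its members 0 passed the limma test of the difference (12 at an unadjusted p under 0.05, all higher with siELOVL7). MAD2L1 (0.61, SE 0.14) and BUB1 (0.59, SE 0.14) had the smallest p-values, 0.202 and 0.227 after adjustment. No other list passed for the difference (camera, adjusted p of at least 0.0784).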

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

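The genes whose ratios differed between the comparisons are given here because the test of the difference passed for them; the knockdown and the diet are not the same contrast, so the difference marks where 2 unlike contrasts part. No array was tested as an outlier within its group of 3. Array weights, whose estimation stopped short of convergence, ran from 0.366 to 4.15 and were lowest on the tumour arrays. Of the alternatives in this part, the array batch as a block, substituted values kept, blocks of spots centred, only spots measured on all 6 arrays, and both changed demands on missing values were chosen after the result was seen.

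Lower in the knockdown ratio were CAMK2N1 (siELOVL7 minus HFD -2.87), AMIGO2 (-1.82) and S1PR3 (-1.60), each with all 3 siELOVL7 arrays below all 3 tumour arrays. Higher were SLC25A33 (1.74), SPOCK1 (1.55), MEAF6 (1.54), TMCO1 (1.36), SMS (1.27), WIPI1 (1.24) and CENPN (1.10). Each kept its sign under all 18 alternatives run for it. CAMK2N1 passed under 15 of them (adjusted p from 5.85e-04 to 0.215) and not without HFD array 2 (0.0788) or 3 (0.0674), nor with the batch as a block (0.215). AMIGO2 passed under 13, S1PR3 and SLC25A33 under 12 each, TMCO1 and WIPI1 under 9 each, MEAF6 under 8, and SPOCK1, SMS and CENPN under 7 each. Leaving out siELOVL7 array 1 or 2, or HFD array 2 or 3, ended the calls of AMIGO2 (adjusted p 0.120, 0.122, 0.0788 and 0.0785 in that order), of S1PR3 (0.215, 0.185, 0.0788 and 0.105) and of SLC25A33 (0.233, 0.185, 0.0862 and 0.157), and of the other genes at adjusted p between 0.0862 and 0.375. Leaving out HFD array 1 ended those of CENPN (0.0655), MEAF6 (0.0731), TMCO1 (0.0508) and WIPI1 (0.0614).

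The real split of the 6 arrays gave 10 genes and the highest of the other 9 splits gave 0, so 1 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached. A spot effect of the same size on all arrays cancels in the difference, but one that differs in size between the comparisons does not. The arrays of a comparison may also share a batch. With siELOVL7 arrays 1 and 2 against the other arrays as a batch, a split seen in which spots were measured, limma called 0 genes (277 at an unadjusted p under 0.05). Some log2 differences stayed about as large: CAMK2N1 -2.74 (SE 0.28, before -2.87, SE 0.19), AMIGO2 -1.83 (SE 0.22, before -1.82, SE 0.14), S1PR3 -1.63 (SE 0.22, before -1.60, SE 0.15) and CENPN 1.08 (SE 0.21, before 1.10, SE 0.14). MEAF6 moved most, from 1.54 (SE 0.19) to 1.21 (SE 0.23). SLC25A33 (1.74 to 1.58), SPOCK1 (1.55 to 1.41), TMCO1 (1.36 to 1.21), WIPI1 (1.24 to 1.14) and SMS (1.27 to 1.20) shrank as well. The fit then rests on siELOVL7 array 3 against the tumours alone, which widened the errors. These genes were called with array 3 in the fit, so a difference that remains on it was partly built in. A test added after the result was seen used 135 genes called without array 3. The test of the difference without that array gave 59 genes, so these 135 came from another selection, whose settings are not given here. On the 135 genes the median position of array 3 was 0.296, from 0 at the tumours to 1 at arrays 1 and 2. These values do not decide whether that batch is a cause, and 1 array does not exclude it. The batch itself is not well borne out: spots measured on array 3 correlated with those of arrays 1 and 2 at 0.139 and 0.148 and with the tumour arrays at 0.166, 0.0388 and -0.0039.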

How the results depend on the processing

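Alternatives that kept the substituted values, centred blocks of spots, used only spots measured on all 6 arrays, took an array batch as a block, or changed the demand on missing values for the difference were chosen after the results were seen; all others were fixed before. The filter on dim spots was not run, since the files hold no intensities, and signal over background limits what can be said of weak spots. Array weights were taken where their estimation stopped short of convergence. Main counts are 1053 higher and 2179 lower with siELOVL7, 547 and 3048 on the high fat diet, 10 for the difference, 1833 overlapping calls of 1 direction and 11 of opposite directions, and 2 and 3 lists. The cause was not tested except where the alternative's own construction shows it.

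With siELOVL7, higher and lower genes numbered 2256 and 1153 after centring, 2322 and 1138 after scaling to 1 median absolute deviation, 1671 and 3580 over single spots, 2127 and 4260 with array weights, and 32 and 223 with an absolute log2 ratio of at least 1. They numbered 1612 and 3825 with the comparison's arrays alone, 402 and 738 with arrays 2 and 3 averaged, 1370 and 4042 with substituted values kept, and 2408 and 1038 with blocks centred. Leaving out an array gave 134 to 641 higher and 359 to 952 lower (array 1: 134 and 359; array 2: 150 and 412; array 3: 641 and 952). On the diet they numbered 1968 and 1074 after centring, 2115 and 1136 after scaling, 917 and 4892 over single spots, 25 and 408 with weights, and 5 and 425 with the log2 limit. The looser threshold gave 895 higher, the comparison's arrays alone 134 and 1493, substituted values kept 894 and 4682, and blocks centred 2100 and 1041. Leaving out an array gave 53 to 442 higher and 518 to 4496 lower (array 1: 1609 lower; array 3: 53 and 518). ELOVL7 kept its fall and its call throughout (-1.04 to -0.69).

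The difference called 6 genes after scaling, 22 with only genes on all 6 arrays fitted, 5 with at least 2 of 3 arrays, 4 with weights, 36 at the looser threshold, 401 with substituted values kept, 19 with blocks centred and 68 with spots on all 6 arrays. Under limma, the array batch as a block called 0 (277 at an unadjusted p under 0.05). Leaving out an array gave 0 to 59 (1, 1 and 59 without siELOVL7 array 1, 2 or 3; 0 without HFD array 2 or 3, where limma gave 1502 and 604 at an unadjusted p under 0.05). With the replicate number as a block 2 genes passed. Numbers are not paired by the labels, and deviations of arrays with the same number correlated at -0.026, -0.0072 and -0.124, with siELOVL7 array 1 correlating best with HFD array 3 (0.120).

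Overlapping calls of 1 direction numbered 3011 over spots, 295 with weights, 3093 at the looser threshold and 3880 with substituted values kept, and 311 to 2924 with an array left out (311, 359 and 825 without siELOVL7 array 1, 2 or 3; 1202, 2924 and 338 without HFD array 1, 2 or 3). Opposite calls numbered 22 after centring, 19 after scaling, 36 at the looser threshold, 107 with substituted values kept, 28 with blocks centred and 21 with spots on all 6 arrays. With an array left out they numbered 2 to 38 (2, 2 and 20 without siELOVL7 array 1, 2 or 3; 17, 38 and 2 without HFD array 1, 2 or 3). The correlation across genes was 0.684 with substituted values kept and 0.643 to 0.743 with an array left out.

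Lists past the threshold with siELOVL7 numbered 1 after centring, 1 after scaling, 1 with the comparison's arrays alone, 5 with fry, 6 with substituted values kept and 1 with blocks centred, and 1 to 2 with an array left out (1 without array 2 or 3). Fry tests a list against 0 and camera tests it against the other genes, and the median gene lay below 0 in both comparisons. Of the lists that passed under fry (adjusted p = 0.0266 each), the cell cycle list pointed up. The elongation and desaturation, lipid transport, blood with muscle and skin, and basal and neuroendocrine lists pointed down. On the diet, lists past the threshold numbered 5 with the comparison's arrays alone and 0 to 6 with an array left out (camera: 0 without array 1, with 3 at an unadjusted p under 0.05; 6 without array 2). Camera gave 0 after centring, scaling or centring of blocks (6 at an unadjusted p under 0.05 in each), fry 0 (8), and camera with an estimated correlation 0 in both comparisons (0 at an unadjusted p under 0.05). The cell cycle list on the diet turned down under fry (0.651), and CENPN on the diet turned from a fall to 0.0095 with blocks centred (not passing); no other named gene and no other list that had passed reversed. Lists that had not passed also turned from up in camera to down in fry, among them ribosomal proteins, the respiratory chain, p53 and inflammation on the diet and fatty acid synthesis, steroid hormones and p53 with siELOVL7. Since fry and camera ask different questions, a turn between them is not a reversal of the same test. The other results for single genes and lists numbered 367, each run under several alternatives. Counted once per result and alternative, 4076 kept their side of the threshold, 1064 lost a call and 19 gained one.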

Other observations

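The tests of the cell cycle list on the difference, of its range with correlated genes, of array 3 on genes called without it, of stroma markers and of a batch shared with the tumours were chosen after the result was seen. For the spot pair and array position tests, the bounds by which they were read were adjusted after a first run. In the knockdown 8 of 30 members of the hypoxia and glycolysis list fell, HIF1A rose and 21 did not pass (8 and 1 adjusted over the list alone; 4 and 3 after centring, camera adjusted p = 0.867). ENO2 (log2 -1.14 ± 0.14), ALDOA (-1.02 ± 0.20) and GAPDH (-0.94 ± 0.15), all glycolytic enzymes, fell, and the hypoxia factor HIF1A read 0.58 ± 0.20. The growth factor list gave 4 rises and 7 falls in 22 genes (4 and 7 adjusted over the list alone; 6 and 4 after centring, adjusted p = 0.993), with the insulin receptor substrate IRS1 (0.75 ± 0.16) and EGFR (0.64 ± 0.05) against the translation repressor EIF4EBP1 (-1.12 ± 0.30) and the kinase AKT1 (-0.78 ± 0.09). The respiratory chain gave 10 rises and 9 falls in 41 (12 and 11 adjusted over the list alone; 14 and 3 after centring, adjusted p = 0.301), with NDUFA5 at 0.88 ± 0.13 and COX6B1 at -0.64 ± 0.07. Ribosomal proteins gave 3 rises and 11 falls in 43 (3 and 11 adjusted over the list alone; 13 and 6 after centring, adjusted p = 0.993), RPS2 reading -1.01 ± 0.11. Among p53 and apoptosis genes 2 of 22 rose and 3 fell (0 and 0 adjusted over the list alone, where 5 had passed in the limma fit of all genes; 7 and 0 after centring, adjusted p = 0.601). The kinase inhibitor CDKN1A fell by 1.10 ± 0.13 there, and did not pass after centring. Inflammation genes gave 2 rises, IL6R (0.81 ± 0.09) and CCL2 (0.54 ± 0.26), and 4 falls in 12 (3 and 4 adjusted over the list alone; 3 and 0 after centring, adjusted p = 0.993).

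Marker lists in the knockdown gave 0 rises and 4 falls in 9 stroma genes (FN1 -1.54 ± 0.07; limma, 1 rise at an unadjusted p under 0.05; 1 and 6 adjusted over the list alone; 1 and 2 after centring, camera adjusted p = 0.538). Of 3 endothelial genes FLT1 (-0.49 ± 0.14) and NOS3 (-0.56 ± 0.37) fell (3 adjusted over the list alone; 0 after centring). Of 7 leukocyte genes 3 fell (3 adjusted over the list alone; 2 after centring, adjusted p = 0.320), CD3D, CD68 and CD79A. Of 8 blood, muscle and skin genes MYH2 (-0.74 ± 0.15) and ACTA1 (-0.67 ± 0.14) fell (2 adjusted over the list alone; 1 fall and 1 rise after centring, adjusted p = 0.562). In limma 0 of 5 adipocyte genes passed (1 at an unadjusted p under 0.05; 0 adjusted over the list alone; 0 after centring, adjusted p = 0.867), PCK1 reading -0.37 ± 0.03. Luminal prostate genes gave 1 rise, CDH1 (0.91 ± 0.13), and 4 falls in 11 (2 and 5 adjusted over the list alone; 3 and 3 after centring, adjusted p = 0.993), with KRT8 at -0.74 ± 0.08. Basal and neuroendocrine genes gave 5 falls in 10 (1 rise and 6 falls adjusted over the list alone; 1 and 3 after centring, adjusted p = 0.112), with GRP at -0.90 ± 0.66. Among the knockdown lists of this part the tests of the growth factor, respiratory chain, p53, inflammation and luminal lists pointed up although their medians were -0.17, -0.02, -0.12, -0.09 and -0.17.

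On the high fat diet NFKB1, a subunit of NF-kappa B, fell by 2.60 ± 0.62. In all 9 of 19 inflammation genes fell and 2 rose, CCL2 (0.57 ± 0.10) and NFKBIA (0.33) (10 and 2 adjusted over the list alone; 3 and 2 after centring, adjusted p = 0.997). Hypoxia and glycolysis gave 1 rise, HIF1A (0.64 ± 0.11), and 5 falls in 31 (1 and 4 adjusted over the list alone; 2 and 1 after centring, adjusted p = 0.903). Growth factor genes gave 2 rises, IRS1 (0.85 ± 0.28) and IGF2R (0.30 ± 0.10), and 4 falls in 27 (1 and 4 adjusted over the list alone; 6 and 2 after centring, adjusted p = 0.977), with FOS at -1.12 ± 0.14 and AKT1 at -1.05 ± 0.08. Among p53 and apoptosis genes RRM2B rose (0.45) and 6 of 21 fell (0 and 6 adjusted over the list alone; 4 and 1 after centring, adjusted p = 0.997), the death receptor TNFRSF10B at -0.63 ± 0.04. The respiratory chain gave 6 rises and 10 falls in 41 (6 and 10 adjusted over the list alone; 13 and 1 after centring, adjusted p = 0.0722), and ribosomal proteins 2 rises, RPL9 (0.49) and RPS7 (0.47 ± 0.12), and 9 falls in 44 (2 and 6 adjusted over the list alone; 15 and 3 after centring, adjusted p = 0.616). On the diet the inflammation, hypoxia, p53, respiratory chain and ribosomal tests pointed up although the medians were -0.53, -0.12, -0.31, -0.04 and -0.10.

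The shared direction of the comparisons has a technical candidate explanation in a dye or spot effect that follows the spotted sequence. Spots of a gene with different accessions correlated at 0.422 of the value of spots with the same accession (95% interval 0.207 to 0.667, which includes 0.5), which is consistent with it. Between the comparisons the same spot correlated at 0.690 and the other spot of the gene at 0.0996, so most of the shared ratio may belong to the spot and not to the gene. For spots with the same accession the values were 0.699 and 0.297, so part of what belongs to the spot did not follow its accession. Steps between blocks of spots are argued against, since r stayed at 0.728 (0.650 to 0.747 with an array left out) after each block was centred. A shared biological response remains open for the part that follows the gene, and different accessions may also detect different transcripts.

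For the cell cycle genes that rose with siELOVL7, a dye or spot effect shared with the tumours would cancel in the difference of the comparisons if it had the same size on all arrays. An effect that differs in size between the comparisons would stay in it. Over all 43 list genes measured on both sides, not only those that rose, the median difference was 0.267 (0.194 to 0.322 with an array left out). It lay above the 95% range of 10000 random lists (0.014 to 0.159). Random lists take genes as independent, and with the correlation estimated within the list (0.119) that range reached 0.263, just below the median but above its lowest value with an array left out, so such an effect may still contribute. The median of 0.267 was taken without centring, and was 0.182 after it. A batch of siELOVL7 arrays 1 and 2 stays open too: on centred arrays, array 3 minus the tumour mean gave 0.240 (0.142 to 0.290 with a tumour array left out; random lists -0.070 to 0.088, up to 0.203 for correlated genes), but that arm is 1 array. Arrays 1 and 2 minus the tumour mean gave 0.180 on centred arrays, within the range for correlated genes (up to 0.211). Higher cell cycle transcripts in the knockdown cells, or lower ones in the tumours on the diet, remain a hypothesis, with an adjusted p of 0.768 for the list when the correlation was estimated.

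SiELOVL7 array 3 lay nearer to the tumour arrays than arrays 1 and 2 did. On a scale from 0 at the tumours to 1 at arrays 1 and 2, it lay at 0.387 (0.372 to 0.474 with a tumour array left out). The scale used the 500 genes that part arrays 1 and 2 most from the tumours. Arrays 1 and 2, each placed with the other as the upper end, lay at 0.742 and 0.822. The tumour arrays, each left out in turn, lay at 0.288, 0.0757 and 0.300. Genes and end points were chosen anew for each array placed, so these scales differ in part. A tumour array under the label of siELOVL7 array 3 is argued against. Array 3 was placed on 135 genes that parted arrays 1 and 2 from the tumours and were called without it. The test of the difference without array 3 gave 59 genes, so the 135 came from another selection, whose settings are not given here. Array 3 lay nearer to arrays 1 and 2 on 37.8% of the 135 genes (36.3% to 52.6% with a tumour array left out). Left-out tumour arrays did so on 14.1%, 20.0% and 4.44%. On siELOVL7 array 3 CAMK2N1 read -2.75 (tumours 0.24, -0.084 and -0.19) and ELOVL7 -1.18. A mixed RNA or an array from outside these groups may be considered and was not tested. A processing batch shared with the tumours may also be considered: the highest correlation of its measured spots with a tumour array was 0.166, against 0.139 and 0.148 with arrays 1 and 2, which decides nothing.

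Sign patterns of the 3 arrays of a comparison number 4, too few for a share under 0.05. The real pattern gave 3232 genes with siELOVL7 and 3595 on the diet, and the highest other pattern 0 in each (1 of 4 patterns gave as many; limma). For the lists, 2 of 4 patterns gave as many as the 2 real ones with siELOVL7 (highest other 2), and 3 of 4 as many as the 3 on the diet (highest other 7). A hypothesis that stroma in the tumours adds transcripts was tested on which genes were measured. Stroma markers made up 11 of 1621 genes measured on all 3 tumour arrays and not all 3 siELOVL7 arrays, COL1A2, COL3A1 and SPARC among them, against 2 of 753 in the reverse, an odds ratio of 2.56 (0.558 to 23.9, Fisher's exact test, 2-sided, p = 0.248), which leaves it open.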
